A study of Homo sapiens with 4 samples.

How the data were processed

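Gene expression was measured by single-cell RNA sequencing in 4 libraries of cultured human endometrial stromal cells. Of these, 3 came from primary cultures, each from another patient, collected at passages 4 to 5 per the labels' protocols, and 1 came from THESC, an endometrial stromal cell line immortalized with telomerase. The cells were grown in culture medium without treatment, detached with 0.25% trypsin-EDTA, passed through a 40 µm strainer and made into libraries with version 3.1 of the Chromium 3' kit, per the labels' protocols.

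The deposited files hold raw UMI counts per gene and cell barcode, 1 matrix per library. Per the file headers, the authors made the counts with Cell Ranger 4.0.0, and the genome was hg38 per the submitters' processing notes. The gene annotation and the way cell barcodes were selected are not given in the sources used here. The deposited matrices listed 36601 genes. XIST, TSIX and the Y-linked genes, 121 in all, were removed before any step, which left 36480. Of these gene identifiers, 34495 were found in GENCODE 29 (GRCh38), 33290 of them under the same name, and coordinates were taken from it. Counts from 3' ends of genes that overlap or have close copies can be split between them, so values of HSPA1B, which has a near-identical copy, are less certain.

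Cells with at least 500 genes detected and at most 20% of UMIs from mitochondrial mRNAs were kept. This left 7451 of 7767 barcodes. Kept cells held 86759755 to 103423397 UMIs per library and a median of 47203 to 55324 UMIs per cell. Scrublet, as built into scanpy, marked 48 cells (0.644%) as doublets with an expected rate of 2%. They were kept. The comparisons of genes and lists, the phase shares and the variable genes were repeated without them, and the clustering was not.

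Counts were summed over the kept cells of each library, since cells of 1 culture are not replicates. The sums were compared with edgeR's quasi-likelihood test (TMM scaling, robust shrinkage) on genes with at least 50 UMIs in at least 1 library, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only 1 THESC library was at hand. The spread was therefore that between the 3 primary cultures (2 residual degrees of freedom), and the lone THESC library was assumed to vary as they do. The p-values cover only the spread between these libraries. The same test was run on cells outside S and G2/M. Levels are given as TMM-scaled counts per 1e6 UMIs (CPM), with the mean and SD of the 3 cultures, or unscaled where a gene was under the count minimum and in the tables of clusters and marker lists. Folds against libraries without a UMI were computed against a floor of 3 counts per library.

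The gene lists, 29 pathway lists and 14 of the 19 cell type lists with at least 5 tested members, were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over 43 lists. With a primary culture left out, only the preset correlation was used. A list with 1 or 2 genes at the floor was also given a median with those genes at their bound, and no list's median moved. A THESC value below all 3 cultures comes up by chance for 25% of genes, and above for as many. The measured shares over all tested genes were 30.2% below and 30.3% above.

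For cell cycle phases, each cell was thinned to 5000 UMIs, the largest of 2000, 5000 and 10000 that kept at least 90% of the cells of each library, and scored with scanpy on 42 S phase and 52 G2/M genes. Shares have 95% Clopper-Pearson intervals. These, the intervals of ratios of counts and the floors cover counting error only. Each library was clustered by itself (2000 variable genes, 30 components, 15 neighbours, Leiden at resolution 0.5). Clusters were named only where at least 3 of the first 10 genes by fold were markers fixed for a type, with 5 CPM added before folds. Overdispersion was computed on thinned counts as the variance minus the mean, divided by the squared mean, for genes with a mean of at least 0.1 UMIs per cell in all 4 libraries. The top 200 genes of each library were compared with 10000 random draws.

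Groups, tests, gene lists, markers, 50 entries of alternatives and the rule for naming genes were fixed before the data were examined, and 7 alternatives were added later. The alternatives covered scaling, the test, low-count filters, cell filters, doublets, depth, the number of cells, leaving out each primary culture in turn, the phase threshold, cluster resolution and the number of variable genes. Named were the 5 genes with the smallest p in each direction, since fewer than 5 passed the threshold, up to 4 members with the smallest p of each list described, 31 fixed genes, up to 15 genes with the best shared overdispersion rank and up to the first 5 genes of each cluster described. HLA genes, genes with common whole-gene deletions and antisense, long noncoding and clone-named genes were left out of naming under this rule, which does not cover the genes chosen after their values were seen.

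The scripts were tested on simulated data. For the comparison of all cells, 200 genes were changed by known folds in counts drawn from the real means. With dispersions shrunken as in the fit, edgeR called 40 of 50 genes changed 4-fold and 29 of 13828 unchanged ones. With dispersions as widely spread between genes as in the data, edgeR and limma voom called 0 genes at any fold, with 36 of 49 genes changed 4-fold at an unadjusted p under 0.05. DESeq2 there called 29 of those 49, and 331 of 13713 unchanged genes (2.41%). A list shifted in simulated data reached a camera adjusted p = 1.01e-22, with 1 other list called, and adjusted p = 0.536 with an estimated correlation. Simulated genes were drawn independently of one another. The list result thus gives no rate of false calls for lists whose members move together. With an estimated correlation the shifted list was missed, so a lack of calls there does not speak against a list. For genes variable in every library, 58 of 60 planted genes were recovered with 0 others among 2000 genes.

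R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9 and matplotlib 3.10.9 were used.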

Results

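Stromal cells of the endometrium, the lining of the uterus, were profiled one cell at a time in 4 cultures. Primary cultures 1, 2 and 3 were each grown from another patient, and THESC is an endometrial stromal line kept dividing by introduced telomerase. No group had been treated, so the design allows a comparison of the line with the primary cultures and a description of the cells within each culture. After filtering, primary culture 1 held 1637 cells and 91556443 UMIs, primary culture 2 held 2022 cells and 100024368 UMIs, primary culture 3 held 2155 cells and 103423397 UMIs, and THESC held 1637 cells and 86759755 UMIs. The median cell had 55324, 51714, 47203 and 51527 UMIs and 6762, 6568, 6433 and 6600 detected genes in these libraries, in that order. The median mitochondrial share was 7.36%, 7.74% and 7.83% of UMIs in the primary cultures and 6.19% in THESC. The summed profiles of the primary cultures correlated across genes with Pearson's r of 0.958 to 0.977, and those of THESC with each primary culture at 0.931 to 0.943, where genes are not independent replicates. Between 6.22% and 10.5% of tested genes lay at least 2-fold apart between primary cultures, and 12.6% to 13.7% between THESC and a primary culture.

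The first comparison asked how gene expression in the line differed from that of the primary cultures. The first genes are named by their p, a rule that picks genes with a small spread between the primary cultures. The genes with the smallest p and a greater level in THESC were CYBRD1, a ferric reductase, ISG20, an interferon-induced exonuclease, HHIP, which binds hedgehog ligands, TNFRSF11B, the secreted decoy receptor osteoprotegerin, and PIK3R1, the regulatory subunit of PI3 kinase. CYBRD1 (ENSG00000071967, chromosome 2, 171522247 to 171558133) stood at 151 CPM in THESC and at 34.8 ± 0.723 CPM (SD, n = 3) in the primary cultures. HHIP (ENSG00000164161, chromosome 4, 144646021 to 144745271) stood at 94.1 CPM against 3.25 ± 0.829, and ISG20 (ENSG00000172183, chromosome 15, 88636153 to 88656483) at 14.4 CPM against 1.09 ± 0.116. TNFRSF11B measured 173 CPM against 46.3 ± 5.40, and PIK3R1 164 CPM against 36.4 ± 5.51. In the other direction stood NFIB, a transcription factor, at 0.125 CPM in THESC and 10.4 ± 0.658 in the primary cultures (ENSG00000147862, chromosome 9, 14081843 to 14398983), and PRDM1, a transcriptional repressor, at 4.37 CPM against 20.9 ± 1.22. ECHDC3 measured 0.057 CPM against 6.04 ± 0.644. NDN, the imprinted gene for necdin (ENSG00000182636, chromosome 15, 23685400 to 23687330), had 0 UMIs in THESC and 1361 in the primary cultures, at least 135-fold lower. RGN had 1 UMI in THESC and 1129 in the primary cultures, a ratio of 337 with a counting interval of 60.4 to 13300.

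None of these differences passed the threshold in edgeR's quasi-likelihood test, which called 0 of 14301 genes. The smallest adjusted p was 0.102. At an unadjusted p under 0.05 stood 1660 genes, 767 of them higher and 893 lower in THESC, where 715 were expected by chance. DESeq2's Wald test called 822 genes (271 higher, 551 lower), including the 10 genes above, limma voom called 0, and 779 of the 822 had an unadjusted edgeR p under 0.05. Without primary culture 1 the number at an unadjusted p under 0.05 was 1101, and without primary culture 2 it was 3149. Without primary culture 3, edgeR called 9 genes (1 higher, 8 lower). NFIB was among them.

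**Figure D1:**
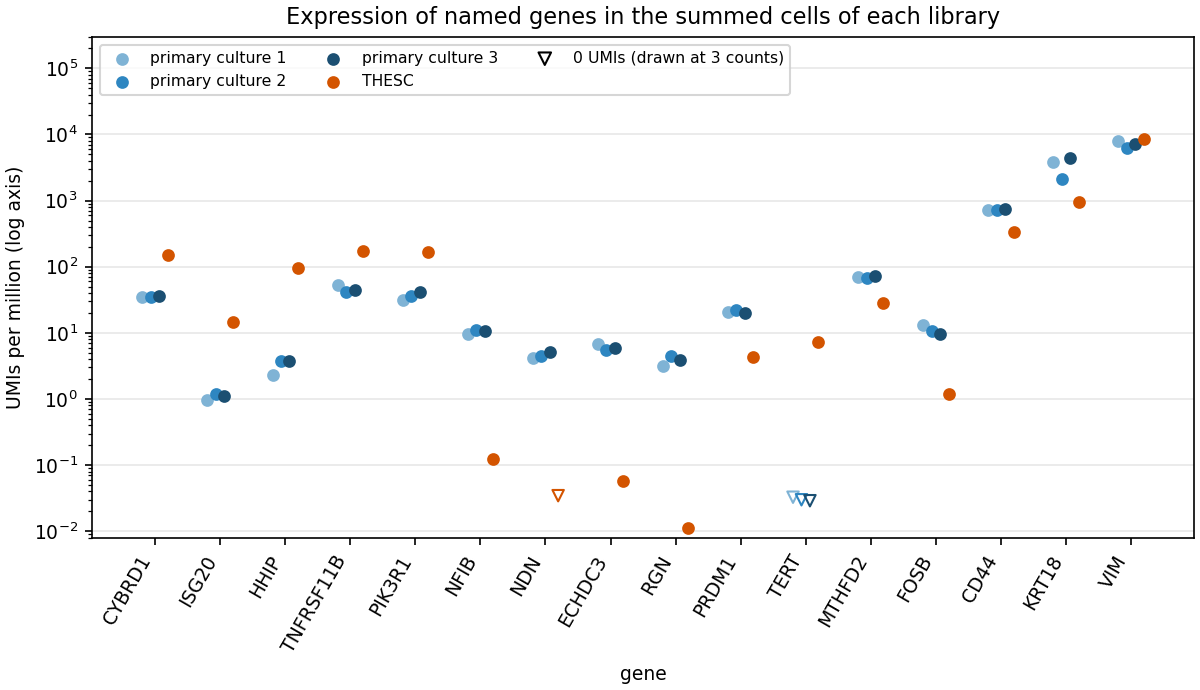
Expression of 16 named genes (x axis) in CPM of the summed cells (y axis, log scale), 1 point per library, with open triangles at 3 counts where a library had 0 UMIs. The first 10 genes are those with the smallest p, for which the 3 primary cultures lie close together and THESC apart, at 151 against 34.8 for CYBRD1. A ranking by p picks such genes, so this pattern follows from the choice.

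TERT, the catalytic subunit of telomerase, was seen only in the line: 629 UMIs (7.17 CPM) in THESC and 0 UMIs in each of the primary cultures, at least 220-fold higher (ENSG00000164362, chromosome 5, 1253147 to 1295069; edgeR adjusted p = 0.173). The other members of the telomere list lay closer together, with POT1, which binds telomeric DNA, at 6.01 CPM in THESC and 4.57 ± 0.174 in the primary cultures. Of the 13 members tested, 1 higher and 0 lower passed when adjusted over the list alone. Fibroblast genes were abundant in every library. VIM, the mesenchymal intermediate filament, stood at 8603 CPM in THESC and 7121 ± 862 in the primary cultures, COL1A1 at 2459 and 3197 ± 695, COL3A1 at 329 and 580 ± 191, PDGFRB at 115 and 92.8 ± 9.93, PDGFRA at 56.8 and 33.6 ± 8.31, and THY1 at 213 and 234 ± 30.2. KRT18, a keratin of simple epithelia, stood at 955 CPM in THESC and 3441 ± 1208 in the primary cultures, while its partner KRT8 stood at 72.1 and 58.0 ± 6.71. EPCAM, an epithelial adhesion protein, stayed under 1 CPM in each library. PTPRC, the leukocyte phosphatase CD45, measured 11.5 CPM in THESC and 1.23 ± 0.510 in the primary cultures. None of the genes in this paragraph passed in edgeR, and 0 of 14301 genes did.

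Genes of the uterine stroma and of its decidual change, the conversion to secretory cells that prepares for implantation, were read as values. PGR, the progesterone receptor, stood at 6.87 CPM in THESC and 5.53 ± 2.99 in the primary cultures, and HAND2, a progesterone-dependent factor, at 49.6 and 37.3 ± 14.5. ESR1 (2 UMIs in THESC, 80 in the primary cultures), PRL (3 and 11), IGFBP1 (26 and 54) and the endothelial gene PECAM1 (0 and 1) were under the count minimum. FOXO1, a factor needed for decidual change, stood at 0.468 CPM in THESC and 4.24 ± 1.48 in the primary cultures, and DIO2, the thyroxine deiodinase, at 6.74 and 137 ± 67.5. DCN, the proteoglycan decorin, stood at 129 and 21.2 ± 7.03, and BMP2 at 0.616 and 2.05 ± 0.600. Of 19 decidualization genes tested, 1 higher (DCN) and 2 lower passed when adjusted over the list alone and 16 did not, and camera did not call the list (adjusted p = 0.269). Among 22 uterine stromal regulators, 0 passed over the list alone, and 2, both lower, in cells outside S and G2/M. TWIST1 stood at 39.4 CPM in THESC and at 13.4, 14.3 and 20.3 CPM in primary cultures 1, 2 and 3, and the homeodomain factor MEIS1 at 24.8 CPM and 14.5 ± 1.57.

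Lists of stress genes leaned lower in THESC, though not all of their members did. Values at an estimated correlation stand beside those at the preset one. That setting missed even a list shifted in simulated data, so its values do not speak against a list. The list of unfolded protein and integrated stress response genes, which includes ATF4 targets of serine and one-carbon metabolism, was lower in THESC by camera (adjusted p = 0.000632; adjusted p = 0.952 with an estimated correlation), with a median log2 fold change of -0.29. Of its 29 members, 19 lay below all 3 primary cultures and 3 above, 0 were called over all genes, and 3 lower passed when adjusted over the list alone. MTHFD2 measured 28.2 CPM in THESC and 70.1 ± 3.24 in the primary cultures, PSAT1 27.5 and 73.2 ± 9.01, PHGDH 57.7 and 127 ± 20.2, and TRIB3 7.07 and 21.5 ± 3.71. The 3 above were PDIA6, CALR and CRELD2, at log2 fold changes of 0.29, 0.17 and 0.30. HSPA5 and HSP90B1, chosen after their values were seen, lay within the range of the primary cultures, at -0.04 each. A shorter stress list, 9 of whose 11 members are in the longer one, was called too (adjusted p = 0.000632; adjusted p = 0.952 with an estimated correlation), with 9 of 11 members below all primary cultures. Immediate early genes, which cells switch on within minutes of a stimulus, were lower in THESC by camera (adjusted p = 0.0174; adjusted p = 0.952 with an estimated correlation; median log2 fold change -0.80). Among 31 of them, 17 lay below all primary cultures and 4 above, and 2 lower passed over the list alone. FOSB measured 1.18 CPM in THESC and 11.1 ± 1.78 in the primary cultures, IER3 113 and 335 ± 42.2, and KLF6 94.5 and 146 ± 7.57, while the heat shock gene HSPA1B stood the other way, at 17.7 and 8.69 ± 1.49. Without primary culture 3 the immediate early list was not called (adjusted p = 0.0577). fry's test of whether a list moves on balance one way called 0 of the 43 lists. Its test of change in either direction, which does not compare a list with other genes, passed 25 of them, among them the unfolded protein list (adjusted p = 0.00888), the shorter stress list (0.0133) and the immediate early genes (0.0360).

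Transcripts of the mitochondrial genome were lower in THESC by camera (adjusted p = 0.0111; adjusted p = 0.952 with an estimated correlation; median log2 fold change -0.25). Of 13 mRNAs, 11 lay below all primary cultures and 0 above, and 2 lower passed when adjusted over the list alone. MT-ATP6 stood at 7125 CPM in THESC and 10400 ± 389 in the primary cultures, MT-CO3 at 8565 and 12340 ± 711, MT-CYB at 5758 and 7842 ± 552, and MT-ND5 at 773 and 990.2 ± 11.8. By fry, the list passed the test of change in either direction, which carries no sign and passed most lists. It did not pass the test of a move on balance one way. These mRNAs make up the mitochondrial share by which cells were filtered, and THESC had both the lowest median share (6.19% against 7.36% to 7.83%) and the smallest part of its barcodes removed (2.09% against 2.84% to 7.63%), so that the list cannot be read apart from this measure of cell quality. Subunits of the same respiratory chain that the nucleus encodes leaned the other way, with 23 of 44 above all primary cultures and 2 below, but the list was not called (adjusted p = 0.051). SDHD stood at 74.5 CPM in THESC and 45.1 ± 6.72 in the primary cultures, COX6C at 457 and 340 ± 30.5, UQCRB at 617 and 493 ± 17.1, and NDUFB3 at 216 and 157 ± 18.4.

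**Figure D2:**
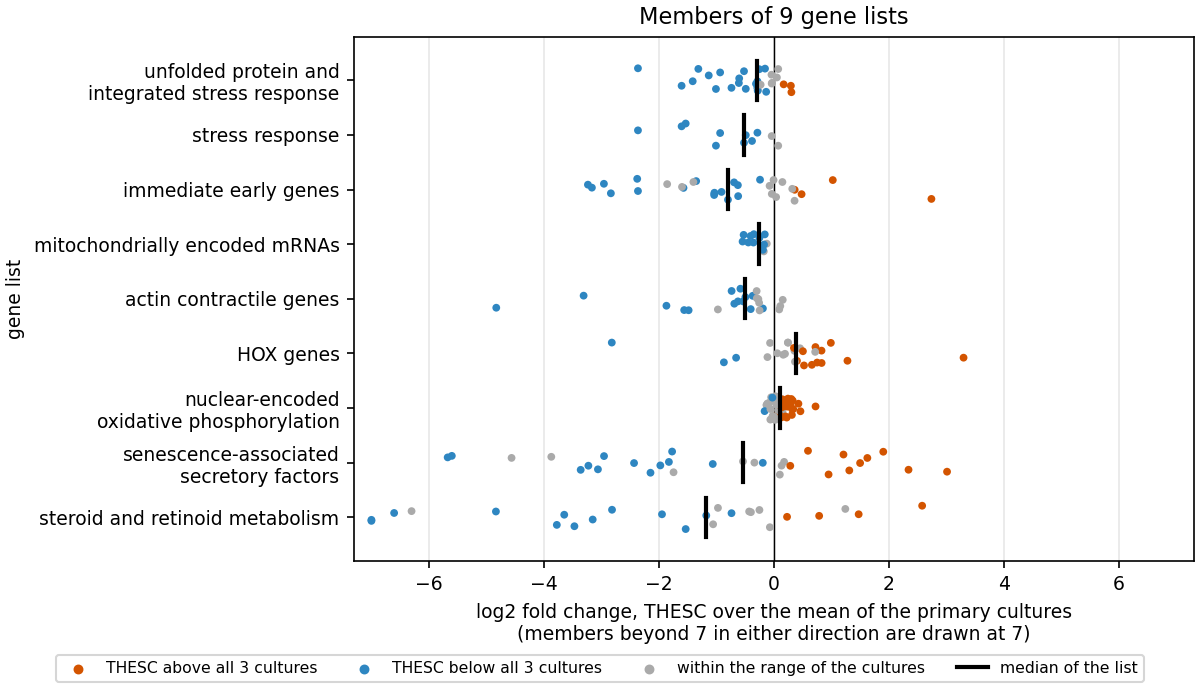
Log2 fold changes of the members of 9 gene lists (y axis), THESC over the mean of the primary cultures (x axis), 1 point per gene, colored by whether THESC lay above, below or within the 3 primary cultures, with black bars at the list medians. The first 5 lists, which camera called at the preset correlation, have medians below 0, at -0.29 for the unfolded protein and integrated stress response genes and -0.80 for the immediate early genes.

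Actin contractile genes were lower in THESC by camera (adjusted p = 0.0159; adjusted p = 0.952 with an estimated correlation; median log2 fold change -0.50), with 14 of 23 below all primary cultures, 0 above and 0 passing over the list alone, and fry's test of change in either direction did not pass (adjusted p = 0.351). MYLK, the kinase of myosin light chain, stood at 134 CPM in THESC and 488 ± 169 in the primary cultures, DES, the muscle intermediate filament, at 1.32 and 13.1 ± 5.26, and CNN2 at 95.1 and 153 ± 12.6. ACTA2 (572 and 1125 ± 725 CPM) and TAGLN (4850 and 5854 ± 2325 CPM) lay within the range of the primary cultures. The contractile genes varied between patients: ACTG2 measured 100.4, 551 and 29.4 CPM in primary cultures 1, 2 and 3 and 7.98 in THESC, and without primary culture 2 the list was not called (adjusted p = 0.138). Matrix genes went both ways. Among 37 matrix glycoproteins and proteoglycans, 3 higher and 1 lower passed over the list alone, with MFAP5, a microfibril protein, at 23.7 CPM in THESC and 0.324 ± 0.268 in the primary cultures, ECM1 at 134 and 60.9 ± 8.80, and MGP, an inhibitor of calcification, at 0.297 and 9.73 ± 5.42. Of 22 collagens, 13 lay below all primary cultures, 5 above and 0 passed over the list alone. COL7A1 stood at 3.65 CPM in THESC and 12.4 ± 2.61 in the primary cultures, COL4A5 at 0.753 and 4.04 ± 1.54, and COL13A1 at 29.2 and 10.3 ± 3.16. Camera called neither of these matrix lists, at adjusted p = 0.271 and 0.17 (for the collagens 0.0251, lower, without primary culture 3), nor the 25 matrix proteases and inhibitors (adjusted p = 0.905), among which the collagenase MMP1 stood at 85.8 CPM against 27.8 ± 9.67 and the stromelysin MMP3 at 1.61 against 82.2 ± 55.2.

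HOX genes, which mark position along the body axis, had a median log2 fold change of 0.38, and 12 of the 26 tested lay above all primary cultures and 3 below (camera adjusted p = 0.051, not called; adjusted p = 0.000367 without primary culture 3). HOXA9 stood at 38.8 CPM in THESC and 21.9 ± 1.47 in the primary cultures, HOXA10 at 92.5 and 65.3 ± 10.4, and HOXB4 at 3.79 and 2.29 ± 0.126. HOXD11 stood at 24.2 and 44.2 ± 1.81, and HOXA13 at 0.821 and 5.81 ± 3.07. HOXC10 and HOXC11, both among the 12, came in large part from a group of 69 THESC cells described below. There they measured 34.8 and 6.14 CPM, against 2.25 and 0.376 in the other THESC cells and 0.395 and 0.335 in the primary cultures. Over the list alone, 1 higher and 1 lower passed. Genes of steroid, retinoid and prostaglandin metabolism had a median log2 fold change of -1.18, with 13 of 25 below all primary cultures and 4 above (camera adjusted p = 0.0601, not called; adjusted p = 0.0307 without primary culture 1 and 0.00788 without primary culture 3). CYP26B1, which degrades retinoic acid, had 0 UMIs in THESC and 355 in the primary cultures, at least 35.7-fold lower. PTGFR, the receptor of prostaglandin F, stood at 10.6 CPM in THESC and 1.78 ± 0.537 in the primary cultures, PTGES, a prostaglandin E synthase, at 12.1 and 4.36 ± 0.579, and AKR1B1, an aldose reductase, at 76.4 and 127 ± 13.3.

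Secreted and receptor genes held the greatest number of members that passed when adjusted over the list alone. Among 31 senescence-associated secretory factors these were 13, 5 higher and 8 lower in THESC, and none passed over all genes. IL6 measured 0.468 CPM in THESC and 4.39 ± 0.690 in the primary cultures, ANGPTL4, an inhibitor of lipoprotein lipase, 3.06 and 16.5 ± 2.92, and IGFBP4 811 and 420 ± 8.92. Camera did not call that list (adjusted p = 0.356). Among 35 growth factors and receptors, 3 higher and 5 lower passed over the list alone. FGF5 stood at 207 CPM in THESC and 35.5 ± 10.7 in the primary cultures, PDGFD at 0.182 and 1.21 ± 0.172, and ERBB3 had a log2 fold change of 2.99. In the WNT pathway 2 of 21 passed, both higher, while 3 higher and 4 lower passed in cells outside S and G2/M. WNT2B stood at 12.5 CPM against 3.41 ± 0.511 and FZD1 at 6.57 against 2.44 ± 0.0796, with the co-receptor ROR2 at 0.0456 against 0.893 ± 0.371, while SFRP4 had 0 UMIs in THESC and 132 in the primary cultures, at least 12.8-fold lower. Of 12 surface markers reported for endometrial mesenchymal stem-like cells, 1 lower passed, CD44 at 339 CPM in THESC and 725 ± 26.1 in the primary cultures, with PODXL at 6.19 and 17.5 ± 5.89, MCAM at 5.68 and 32.2 ± 23.7, NT5E at 239 and 196 ± 22.4 and SUSD2 at 1.21 and 1.41 ± 1.15. Among 31 p53 targets and cell cycle inhibitors 0 passed. The list's median log2 fold change was 0.10, while its mean was below 0. GDF15 had a log2 fold change of -2.15, and FAS measured 48.9 CPM in THESC and 26.2 ± 3.67 in the primary cultures, CDKN1A 175 and 157 ± 14.5, and CDKN2A 35.4 and 28.9 ± 2.64. Camera called no further list among the 43 with all libraries, with adjusted p from 0.051 to 0.905. Beyond the HOX, steroid, collagen and S phase lists, calls of lower lists were gained for the contractile myofibroblast list without primary culture 1 (adjusted p = 0.0148) and 3 (0.00175), the decidual stromal list without primary culture 1 (0.04), and the inflammatory fibroblast (0.0168) and dissociation stress lists (0.0149) without primary culture 2. All 11 dissociation stress genes are also among the immediate early genes.

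The second comparison was limited to cells outside S and G2/M, so that the share of dividing cells would not enter. For HHIP it gave a log2 fold change of 5.03 (4.86 in all cells), for CYBRD1 2.16 (2.12), for MTHFD2 -1.35 (-1.31) and for FOSB -3.02 (-3.23), near those of all cells. Cycle genes moved more, with the median of the G2/M cycling marker list at -0.314 (0.038 in all cells). These cells were picked by scores of the S phase and G2/M genes, many of which are also cycling markers. Values and calls of these lists in the picked cells thus depend on the selection. Camera called 8 lists. These were the 5 of the first comparison, with the contractile myofibroblast list lower (adjusted p = 0.0491) and the nuclear-encoded respiratory chain (adjusted p = 0.0239, 24 of 44 above all primary cultures and 1 below) and HOX genes (adjusted p = 0.0491, 11 of 25 above and 3 below) higher in THESC. Each had an adjusted p = 0.886 with an estimated correlation. By fry, 0 lists moved on balance one way and 26 changed in either direction. Of the 17 contractile myofibroblast genes, 14 are also among the actin contractile genes. The respiratory chain and HOX calls were lost without primary culture 1 (adjusted p = 0.0502 and 0.104) and without primary culture 2 (0.119 and 0.0854), and the mitochondrial mRNA call without primary culture 1 (0.0502). Both contractile calls were lost without primary culture 2, at adjusted p = 0.177 and 0.245. Calls of lower lists were gained for the steroid and retinoid genes without primary cultures 1 and 3 (adjusted p = 0.0477 and 0.0104), for the S phase and G2/M genes (0.0322 and 0.00163), the S phase and G2/M cycling marker lists (0.00097 and 0.000218) and the dissociation stress list (0.00695) without primary culture 2, and for the collagens without primary culture 3 (0.0281). edgeR called 0 of 13596 genes, with 1622 at an unadjusted p under 0.05, 1074 without primary culture 1 and 2891 without primary culture 2. DESeq2 called 760 and limma voom 0, and edgeR called 9 without primary culture 3.

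Dividing cells were found in all 4 libraries. Cells called in S or G2/M made up 40.3% of primary culture 1 (95% Clopper-Pearson interval 37.9 to 42.7%), 25.4% of primary culture 2 (23.4 to 27.4%), 38.0% of primary culture 3 (35.9 to 40.1%) and 28.6% of THESC (26.4 to 30.9%). The primary cultures had a mean of 34.6% ± 8.01 (SD, n = 3), and THESC lay 5.97 points below it, within their range. The two-sided exact permutation test over the 4 placements of the lone library gave p = 1.0, and its smallest possible p is 0.25. Without primary culture 2 the difference was -10.5 points, and without primary culture 1 it was -3.11 points. The phase is a range of a score, and 157, 108, 187 and 109 cells lay within 0.05 of the threshold in the 4 libraries, in that order. In the summed counts, which do not depend on phase calls, MKI67 measured 102, 62.5 and 109 CPM in the primary cultures and 86.2 in THESC, TOP2A 94.6, 77.6, 97.9 and 105, and PCNA 67.1, 47.6, 67.4 and 69.1. Camera called neither the S phase genes (adjusted p = 0.441) nor the G2/M genes (adjusted p = 0.551). Without primary culture 2, which had the fewest dividing cells, the S phase genes and the S phase cycling markers were called lower in THESC at the preset correlation (adjusted p = 0.00113 and 0.000669), and an estimated one was not tried there.

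**Figure D3:**
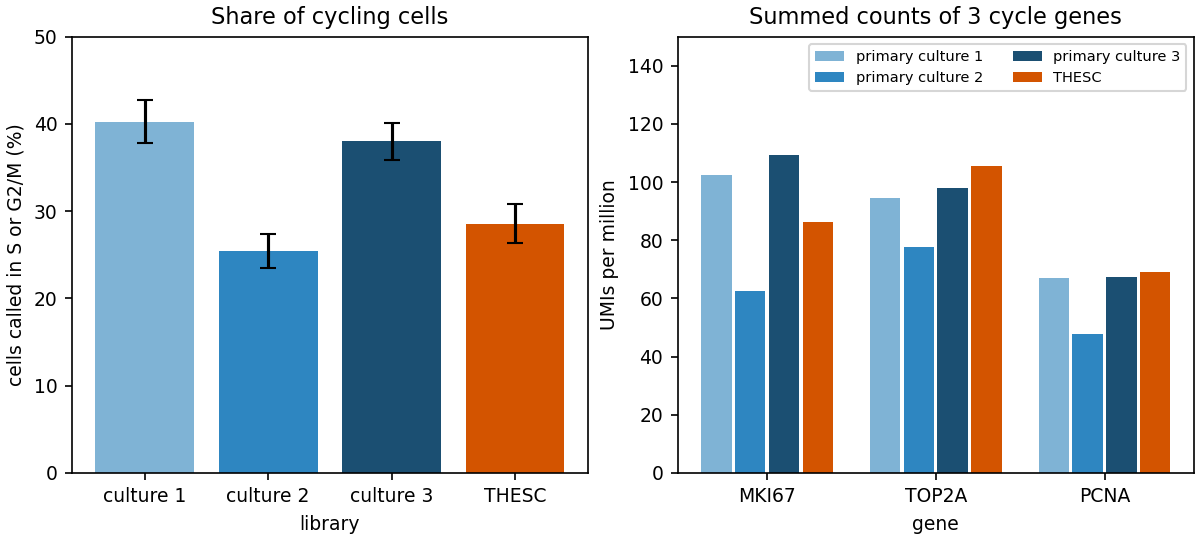
Left, the share of cells called in S or G2/M in each library (y axis, percent), with 95% Clopper-Pearson intervals as error bars, and right, CPM of 3 cycle genes in the summed cells (y axis), 1 bar per library. THESC, at 28.6%, lies between primary culture 2 at 25.4% and primary culture 1 at 40.3%.

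To see how far any one library stood from the other 3, each was set in turn as the lone one. With a primary culture alone, THESC was among the other 3 and entered their spread. Counts for the primary cultures are thus not on 1 scale with that for THESC. edgeR called 0 genes in each placement. At an unadjusted p under 0.05 stood 173 genes with primary culture 1 alone, 279 with primary culture 3, 1282 with primary culture 2 and 1660 with THESC. DESeq2, added as a tool after the data were seen, called 24, 46, 361 and 822 genes in the same order. Primary culture 2, with ACTG2 at 551 CPM and MCAM, a perivascular surface marker, at 59.5 CPM (19.6 and 17.6 in the other primary cultures), thus stood farther from the rest than the other primary cultures did, and 4 placements cannot give a share under 0.05.

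Within each culture, cells fell into 8, 6, 8 and 8 clusters in primary cultures 1, 2 and 3 and THESC, 30 in all. The cell cycle named 10 of them, 7 as G2/M cycling-like and 3 as S phase cycling-like, and the other 20 stayed unnamed under the marker rule. G2/M clusters led by genes of the spindle and kinetochore shared 44 to 46 leading genes among primary cultures 1 and 3 and THESC, and 36 to 38 with that of primary culture 2. The one of primary culture 1 (281 cells, led by CENPE, UBE2C, AURKA, CENPF and ASPM) shared 46 of its 50 leading genes with that of primary culture 3 and 45 with that of THESC (150 cells, led by UBE2C, TOP2A, ASPM, PLK1 and AURKA), where chance gives 0.273 and 0.278. The S phase cluster of primary culture 1 (219 cells, led by the histone genes HIST1H1B and HIST1H1D and by FAM111B, CDC6 and MCM10) shared 39 of 50 with that of THESC. Outside the cycle, overlaps were smaller. The greatest, 24 genes, joined clusters of cells with few UMIs led by LRRC75A in primary culture 3 and THESC. A cluster of primary culture 1 led by PPP1R14A, an inhibitor of myosin phosphatase, with C11orf96, PTGDS and FAM43A (420 cells, 25.7% of the culture) shared 20 leading genes with one of primary culture 3 (761 cells, 35.3%, led by CLIC3, NPPB, IGFBP5, CEMIP and GDF15) and 15 each with one of primary culture 2 (416 cells, 20.6%, led by PPP1R14A, TPD52L1, C11orf96, SCUBE3 and PTX3) and one of THESC (445 cells, 27.2%, led by ACTC1, CLIC3, ACTA2, POSTN and LMCD1). The latter clusters of primary culture 3 and THESC shared 15 leading genes. That of primary culture 2 shared only 2 with that of primary culture 3 and 4 with that of THESC, so no single state of all 4 cultures was shown. Cells led by IGFBP5 and the keratin KRT17, with ACTG2 and MGP among their first 10 genes, formed a cluster of 128 cells in primary culture 1 and of 440 cells in primary culture 2, which shared 17. When all libraries were clustered together, 1590 of the 1637 THESC cells (97.1%) fell into 3 clusters that held 0 cells of the primary cultures. Of the other 9 joint clusters, 3 drew 90.7% to 98.6% of their cells from primary culture 2, 1 drew 96.7% from primary culture 1 and 1 drew 98.9% from primary culture 3.

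**Figure D4:**
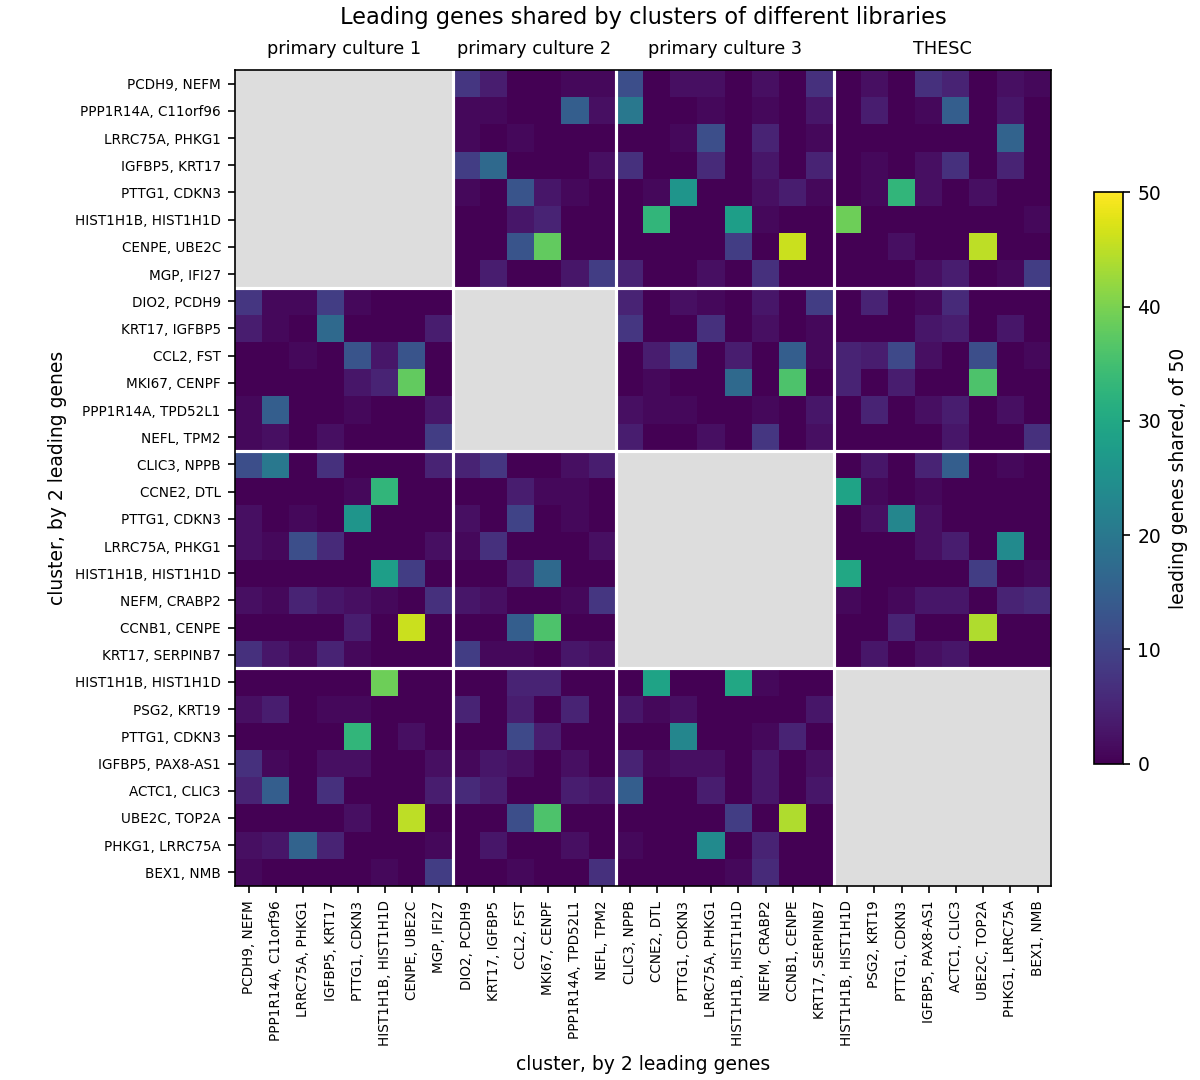
Number of leading genes, of 50, shared by each pair of clusters from different libraries (color), with clusters on both axes named by 2 leading genes and white lines between libraries. The 3 brightest squares join G2/M clusters of primary cultures 1 and 3 and THESC, which share 44 to 46 of 50 genes, followed by an S phase pair at 39, and pairs within a library were not compared and are gray.

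The genes that varied most between cells were largely shared. Of 4706 genes considered, 106 were among the 200 most overdispersed in all 4 libraries, where random draws gave a mean of 0.0132 and at most 1. Cell cycle lists held 47 of the 106, including UBE2C, TOP2A, CDK1, CENPE, ASPM, HIST1H4C, AURKA, HMMR, CENPF, PLK1 and MKI67. Outside those lists, 59 remained. Not all of them are apart from the cycle: CEP55, PBK and KNSTRN were among the leading genes shared by the G2/M clusters of primary cultures 1 and 3. G0S2, an inhibitor of triglyceride lipase, ranked within the first 4 genes of every library, the chemokine CCL2 within the first 10, the pentraxin PTX3 within 14 and the hypoxia-induced ANKRD37 within 17. In thinned cells G0S2 had a mean of 1.29, 0.232 and 0.650 UMIs in the primary cultures and 1.52 in THESC. With cells outside S and G2/M alone, 64 genes were shared, 5 of them in cycle lists and 59 not. These 59 are another set than the 59 above, and PTX3, CEP55, PBK and KNSTRN are not in it. Those 64, of 4539 genes considered in these cells, included 6 senescence-associated secretory factors (among them CCL2) and 5 matrix proteases and inhibitors. Among the genes considered in all cells these lists held 10 and 14 members. The nuclear-encoded respiratory chain, with 44, had 0 shared, which is near the share of all genes. Genes are not independent replicates, so these counts describe the libraries.

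Markers of other cell types were read in each library to see whether other cells had come along. No cluster was named for perivascular, epithelial, endothelial, immune, erythroid, mesothelial or neural cells. At least 3 ciliated epithelial markers or 3 erythroid markers were found in 0 cells of any library, which allows, at 3 of the 1637 THESC cells, a share of up to 0.183% with such counts and sets no limit on cells of these types. At least 3 of 14 endothelial markers had a UMI in 3.02% to 5.50% of cells of the primary cultures and 5.68% of THESC cells, at 31.4 to 50.5 summed CPM. For the immune list these shares were 14.8% to 20.9% and 34.0%, at 210 to 587 and 1126 summed CPM, and of its 6 tested members 3 lay above and 2 below all primary cultures in THESC. Mesothelial markers reached at most 1.21% and neural markers at most 0.418% of cells. Epithelial keratins are also made by cultured stromal cells: 3 epithelial markers had a UMI in 83.6% to 87.7% of the cells of every library, and perivascular markers in 40.7% to 63.8%. With medians of at least 47203 UMIs per cell, and free RNA in the droplets not measured, such shares cannot be read as cells of these types.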

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

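No explanation was tested in this part, and the test of gene lists with all barcodes was chosen after the data were seen. The barcodes that the cell filter removed, which entered only an alternative with all barcodes, are a signal outside the data that the report compares. The filter removed 50 of 51, 153 of 167, 57 of 63 and 33 of 35 of them for a mitochondrial share over 20% in primary cultures 1, 2 and 3 and THESC, so a share above that follows from the filter. The median mitochondrial share of their UMIs was 91.5% in primary culture 1 (51 barcodes removed), 90.9% in primary culture 2 (167 barcodes), 75.1% in primary culture 3 (63 barcodes) and 92.6% in THESC (35 barcodes), against 6.19% to 7.83% in kept cells. They were 2.09% to 7.63% of the barcodes of a library. With all deposited barcodes kept, edgeR called 0 genes and camera called 5 lists in all cells, as with the filter.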

How the results depend on the processing

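Chosen after the data were seen were the tests of gene lists under other cell filters, fry's test of change in either direction and DESeq2 with each library in turn as the lone one. The 0 genes called by edgeR in all cells were also 0 with other scaling, limma voom, non-robust shrinkage, a filter of 10 CPM, each cell filter, equal cell numbers and without ribosomal and mitochondrial mRNAs. This says nothing about stability, since edgeR and voom called 0 genes at any fold in simulated data with dispersions as widely spread as in these, and the number at an unadjusted p under 0.05, 1660, was 862 to 1686 under those settings. Without a filter on low counts 35 genes were called, with DESeq2 822, and with thinned counts 1 (HHIP), and 0 to 9 without each primary culture in turn. In non-cycling cells these counts were 71, 760, 1 and 0 to 9. The cause was not tested. With each library in turn as the lone one, DESeq2 called 24, 361, 46 and 822 genes for primary cultures 1, 2 and 3 and THESC, where edgeR called 0. Camera at an estimated correlation missed even the list shifted in simulated data, so its lack of calls does not speak against a list. At the preset correlation camera called 5 lists in all cells and 8 in non-cycling cells. An estimated correlation and fry's test of a move on balance one way left 0 in both, fry's test of change in either direction passed 25 and 26 lists, and leaving out each primary culture in turn gave 8 in each case for all cells and 6 to 10 for non-cycling cells. Other cell filters gave 5 in all cells and 10 in non-cycling cells, where G2/M genes joined. G2/M genes had themselves entered the scores that picked the non-cycling cells. The cause was not tested. Of 688 comparisons of a list and an alternative, 628 were on the same side of the threshold, and no list called at a setting had the opposite direction with all 4 libraries. The S phase lists leaned higher without primary culture 1 (adjusted p = 0.858) and were called lower without primary culture 2 (0.00113 and 0.000669). THESC had fewer cells in S or G2/M than the mean of the primary cultures at each setting, by -2.76 to -6.10 points, and by -3.11 to -10.5 without each primary culture in turn. Genes variable in all 4 libraries were 106 with the top 200 of each library, 61 with the top 100, 208 with the top 500 and 64 in cells outside S and G2/M, with 113 to 122 when 1 primary culture was left out. Clusters numbered 30 over the libraries, 23 at resolution 0.3, 51 at resolution 1.0 and 12 when all were clustered together. Of the named genes, MKI67, PGR, SUSD2, TAGLN and TINF2 changed sign under some alternative in all cells, each without passing a threshold, and the shift of the median log2 fold change by other scaling was at most 0.0225. No paired analysis was possible because no label links the 1 THESC library to a patient of a primary culture. Genes under the count minimum, such as PRL with 3 UMIs in THESC, cannot be compared.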

Other observations

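Chosen only after the result was seen were the tests for doublets by depth in a group of THESC cells and the reading of MKI67 and TOP2A there. So were the test of HOXC10 in cells clustered without HOX genes and the tests on a different share of dividing cells. The test of immediate early genes under the stricter cell filter and the one on handling of the THESC library were chosen then too. The genes named for groups and clusters of cells here were also chosen after their values were seen.

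A small group of THESC cells carried another HOX profile than the rest of the line. A cluster of 101 of the 1637 THESC cells was led, antisense genes aside, by IGFBP5, KRTAP2-3, G0S2, BEX1 and SFRP1, and 69 of these cells (4.22% of THESC, Clopper-Pearson interval 3.29 to 5.30%) also formed a cluster when HOX genes were left out of clustering. In those 69 cells HOXC10 measured 34.8 CPM against 2.25 in the other THESC cells, and HOXC11, HOXC6, HOXC8 and HOXC9 were higher as well, by ratios of 3.49 to 16.3. HOXD11 measured 0.227 CPM (1 UMI) against 25.7 (2117 UMIs), and HOXD10 had 0 UMIs against 1195. HOXC10 had a UMI in 87.0% of these cells and in 3.76% of the others. Median depths were 61874 and 50792 UMIs in the group and in the THESC cells outside the cluster of 101. Outside that cluster 2.02% of cells had a UMI of HOXC10, and free RNA in the droplets was not measured. SFRP1, a secreted inhibitor of WNT signals, was 20.1 times the level of the other cells (interval 16.7 to 24.2). WNT2 was at 0.053 times, the cardiac actin gene ACTC1 at 0.0107 times, ISLR at 0.0384 times and RARRES2 at 0.0268 times that level. Of the 69 cells 37.7% were called in S or G2/M, against 28.2% of the other THESC cells, and 42.0% had a UMI of MKI67, against 33.4% outside the cluster. The level of MKI67 went the other way, at 41.4 CPM in the 69 cells, 1.56 CPM in the other 32 cells of the cluster and 92.4 CPM in THESC cells outside it.

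Antagonists of bone morphogenetic proteins (BMPs) and interferon genes were read as values in the line and the primary cultures. FST, which binds activin and BMPs, stood at 565 CPM in THESC and 145 ± 56.2 (SD, n = 3) in the primary cultures and NOG at 8.60 and 3.47 ± 0.841, with the NOTCH target HES1 at 4.93 and 9.78 ± 1.44. None of these 22 genes passed when adjusted over the list alone, and camera did not call the list (adjusted p = 0.17). Among 37 interferon-stimulated genes, ISG15 stood at 226 CPM in THESC and 129 ± 9.24 in the primary cultures and the guanylate-binding protein GBP1 at 42.7 and 79.9 ± 10.7, and camera did not call the list (adjusted p = 0.716). For the lower mitochondrial mRNAs in THESC, cell quality stays open, since the share that the cell filter limits is the sum of these mRNAs and no separate test was made.

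The first pattern weighed is the group of THESC cells with another HOX profile, for which the design gives no biological group to set against technical ones. Doublets are argued against for the 69 cells by a median UMI count 1.22 times that of THESC cells outside the cluster, but for the other 32 it was 1.68 times, so that doublets of 2 cells of the group stay open, though Scrublet marked 0 of the 101. Doublets of a cell of the group with a THESC cell outside it also stay open for the 32 by WNT2 and ISLR. These summed to 21.6% (counting interval 17.0 to 27.1%) of their level outside, against 4.8% in the 69 cells. HOXC10 at 42.6 CPM (34.8 in the 69) and HOXD11 at 2.73 CPM (26.4 outside) cannot decide this. HOX genes had helped to pick the 32 cells. Cells without TERT, those of the primary cultures with their 0 UMIs included, are argued against by TERT. Its level in the 101 cells was 196% (interval 156 to 245%) of that in the THESC cells outside the cluster. Cells from outside the line that express TERT could not be told apart this way. HOX genes as the sole ground of the clustering are argued against for the 69 cells, where HOXC10 was 15.5 times as high (12.4 to 19.3) though no HOX gene had been used, but not for the other 32, since only 68.3% of the cluster held together, under the 80% set beforehand.

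A second lineage within the line may be present in the 69 cells, as a hypothesis from 1 library. A gained or lost chromosome could mark it. The median log2 ratio of the genes of each autosome, these cells over the other THESC cells, was at most -0.0437 away from 0 (chromosome 15), so no gain or loss of a whole chromosome was seen, and smaller changes could not be tested this way.

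The second pattern is the set of lower stress and immediate early genes in THESC. Damaged or shallow cells are argued against only as far as a stricter filter removes them. That filter asked for at least 2000 genes and at most 10% mitochondrial UMIs per cell. It left 85241446 of 86759755 UMIs in THESC, so the sums could move little. In primary cultures 1, 2 and 3 it left 85513176 of 91556443, 87409722 of 100024368 and 93210305 of 103423397. The median log2 fold change of the unfolded protein and integrated stress list then kept 108% of its size (bootstrap interval over members 90.2 to 111%). That of the immediate early list kept 98.7% (93.4 to 160%). A different share of dividing cells is argued against as well, with 96.5% (84.0 to 116%) and 102% (91.9 to 307%) kept in non-cycling cells. Handling of the single THESC library cannot be told apart from the cell source, because immediate early genes (median log2 fold change -0.80) respond to detachment from the plate and only 1 THESC library was made. A difference between the line and primary cells, which the design names, likewise stays open and untested.

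The third pattern is 2 kinds of clusters with few UMIs, for which no biological explanation was tested. Clusters led by LRRC75A and PHKG1 held 158, 218 and 171 cells of primary cultures 1 and 3 and THESC at medians of 14665 to 16385 UMIs, and the nuclear-retained RNAs TUG1, KCNQ1OT1 and PVT1 took at least 1.87 times the share of UMIs there as in other cells. Cells that lost cytoplasm stay open as a candidate explanation, since MALAT1, also retained in the nucleus, took only 1.13, 1.69 and 1.30 times the share, and the share of ribosomal protein mRNAs was lower in the clusters of primary cultures 1 and 3 but higher in that of THESC (18.3% against 17.1%). Clusters with a median mitochondrial share under 1% held 24, 60, 66 and 21 cells of the 4 libraries, and the same RNAs took at most 0.234 times the share of other cells, as fragments without a nucleus would have. The counts behind that ratio were 1 to 11 UMIs per cluster, with intervals up to 0.51.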
